A study of Mus musculus with 6 samples.

How the data were processed

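RNA was measured by sequencing in 6 libraries of lymphocytes isolated from Hepa1-6 tumors in mice, 3 from mice given the mock guide and 3 from mice given the guide against SLC43A2. Per the labels' protocols, libraries were made from 1 ug of total RNA with the Illumina TruSeq RNA kit, which does not mark strand. The same protocol text speaks of retinas, although the other labels give tumor as the tissue and lymphocytes as the cell type; the text therefore may not describe these samples. Groups and replicate numbers were taken from the sample titles.

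The values are gene-level TPM that the authors deposited in a single table of 57180 genes, rounded to 2 decimals and scaled to the same sum in each library. Per the submitters' processing notes, Bowtie 0.12.2 and the genome build mm8 were used, with no role stated. The counting tool, the annotation release and any filter are not given in the sources used here. Of the gene identifiers in the table, 51884 (90.7%) are in GENCODE M21, an annotation of GRCm38, and many of them are newer than the mm8 build, so the build behind the table is uncertain. Coordinates, transcript lengths and strand overlaps were taken from GENCODE M21. TPM keeps no read count, so depth and counting error are unknown, no interval or floor is given, and a gene at exactly 0 is described as listed at 0. A TPM is a share of its library, so a change in abundant transcripts moves all other values.

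Differences were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with a mean-variance trend, two-sided) on log2(TPM + 1), over the 13759 genes (24.1% of the table) with a mean of at least 1 TPM over the 6 libraries. P-values were adjusted by the Benjamini-Hochberg method over all genes tested, with a threshold of 0.05. Fold changes on the log2(TPM + 1) scale understate the change of low genes; folds of TPM are ratios of group means. Means carry the SD of 3 libraries. Slc43a2 and shares of a library were also tested with an exact two-sided permutation test, whose smallest p with 3 against 3 is 0.1.

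Gene lists were tested with camera at a preset inter-gene correlation of 0.01, adjusted over the 29 lists with at least 5 measured members; an estimated correlation and fry were alternatives. The 33 lists covered amino acid transporters, methionine cycle and polyamine synthesis, serine and folate genes, histone and DNA methyltransferases, STAT5 targets, ATF4 targets, T cell identity, cytotoxic, exhaustion, activation, naive and memory and regulatory T cell genes, NK cells, B cells, plasma cells, macrophages, neutrophils, dendritic cells, hepatocytes and hepatoma, fibroblasts, endothelium, erythroid cells, photoreceptors, type I and gamma interferon responses, MHC class II, cell cycle, Wnt targets, glycolysis, oxidative phosphorylation, immediate early genes, mitochondrially encoded mRNAs and ribosomal proteins. The test, the lists, most of the other settings and the rule for named genes were chosen before the data were examined. The rule named Slc43a2, the 10 largest rises and 10 largest falls past the threshold whose groups did not overlap, and from each list up to 4 members, those of largest rise and fall past the threshold, or else those of smallest p. The rule left out predicted genes and single antigen receptor segments, and added the most abundant member of each cell type list. Some genes that the rule takes are not reported here.

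Alternatives covered pseudocounts of 0.1 and 0.5, no filter or a mean of at least 5 TPM, median-of-ratios scaling, quantile normalization, removal of antigen receptor, mitochondrial and hemoglobin genes or of hepatocyte genes, other variance models, array weights, a replicate block and leaving out each library. Scaling to T cell receptor transcripts, removal of genes of other cell types and removal of trends with transcript length and GC, for the 94.1% of tested genes with both values, were added after the data were seen. The fit was tested on simulated values for 13759 genes, of which 200 were changed. It recovered 0% of genes changed by 0.5, 16.4% of those changed by 1 and 77.3% of those changed by 2 on the log2 scale. There were 2 false calls. The simulated noise was independent between genes and few genes were changed, whereas 6199 passed in the data. These rates therefore do not describe the power or the false calls of the real comparison.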

Results

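The data are RNA-seq profiles of lymphocytes isolated from tumors of mice carrying Hepa1-6, a mouse hepatoma cell line. The mice received by tail vein a delivery system named TREND, loaded with plasmids for CasRx, an RNA-targeting CRISPR nuclease that cuts transcripts rather than DNA. The guide RNA was either a mock guide (Mock sgRNA, 3 libraries) or a guide against SLC43A2, a transporter of large neutral amino acids including methionine (SLC43A2 sgRNA, 3 libraries). The deposited values are TPM (each transcript's length-adjusted share of its library) for 57180 genes, scaled to the same sum in each library, so the sequencing depth of each library is unknown. Of these genes, 13759 had a mean of at least 1 TPM over the 6 libraries and were tested. Across these genes, log2 values correlated at 0.919 to 0.932 between Mock sgRNA libraries, at 0.949 to 0.952 between SLC43A2 sgRNA libraries, and at 0.837 to 0.883 between the groups.

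The targeted gene was examined first. Slc43a2 (ENSMUSG00000038178; GRCm38 chromosome 11, 75531694 to 75577575, plus strand) was low in these lymphocytes. It stood at 6.68, 4.18 and 4.79 TPM in Mock sgRNA replicates 1, 2 and 3 and at 3.5, 2.4 and 4.15 TPM in SLC43A2 sgRNA replicates 1, 2 and 3. The means were 5.22 ± 1.30 and 3.35 ± 0.885 TPM (SD, n = 3 each). The log2 difference of -0.52 (SE 0.23) did not pass the threshold (limma, adjusted p = 0.113). All 3 SLC43A2 sgRNA values lay below all 3 Mock sgRNA values, the closest being 4.15 and 4.18 TPM. This gives an exact two-sided permutation p of 0.1, the smallest that 3 against 3 can reach. The groups did not overlap for 57.0% of all tested genes, so such separation is common here. The series title describes the system as tumor-specific, and the RNA measured here is from lymphocytes. Exons of Slc43a2 share 922 of their 10042 bases (9.2%) with Gm45606 on the opposite strand. Reads of that shared stretch cannot be assigned to either gene without strand information. Gm45606, named after its values were seen, fell past the threshold, from 6.66 to 2.68 TPM (log2 change -1.05, limma adjusted p = 0.0033).

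The comparison asks how the RNA of tumor-infiltrating lymphocytes differed between mice given the SLC43A2 guide and mice given the mock guide. Sex-linked transcripts differed too. The Y-linked Eif2s3y stood at 51.4 TPM in Mock sgRNA and 1.03 TPM in SLC43A2 sgRNA, and Xist rose by 1.19. The groups may therefore differ in the sex of their cells, and the guide cannot be separated from such a difference in this design. Most measured genes of glycolysis (16 of 17), the amino acid starvation response (16 of 19), T cell activation (12 of 16) and the interferon gamma response (16 of 23) rose in the SLC43A2 sgRNA libraries. Most markers of B cells, plasma cells, macrophages, neutrophils, red blood cells and NK cells fell, as did MHC class II genes. These lists passed a set test at a preset inter-gene correlation, and 0 of 29 lists passed with an estimated one (smallest adjusted p = 0.0570). The costimulatory receptor gene Tnfrsf4 (OX40) stood 8.99-fold higher, from 179 ± 37.8 to 1606 ± 218 TPM (SD, n = 3 each). The chemokine gene Ccl5 stood 24.2-fold lower, from 2919 ± 95.6 to 121 ± 2.23 TPM.

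In all, 6199 of the 13759 tested genes (45.1%) passed an adjusted p of 0.05 with limma, 3139 of them higher and 3060 lower in SLC43A2 sgRNA. By at least 1 on the log2 scale, 1134 were higher and 1836 lower. Among the 10463 protein-coding genes tested, 2940 rose and 2024 fell. The groups did not overlap for 7845 genes (57.0%, where chance gives 10%). With libraries scaled to their T cell receptor constant-region transcripts, 62.4% of the calls were higher, against 50.6% with TPM as deposited. The share was 60.6% among genes of at least 5 TPM, and 44.4% both with no filter and without antigen receptor, mitochondrial and hemoglobin genes. The composition of the libraries also differed, with no overlap between the groups in any of these measures (n = 3 each, exact permutation p = 0.1). Protein-coding transcripts made up 77.9% ± 1.13 of the Mock sgRNA and 86.6% ± 0.338 of the SLC43A2 sgRNA libraries, and small nuclear and nucleolar RNAs 3.15% ± 0.677 and 1.04% ± 0.0700. The nuclear RNA Malat1, named after its values were seen, made up 1.09% ± 0.135 and 0.417% ± 0.0867, and mitochondrial ribosomal RNAs 0.703% ± 0.170 and 0.195% ± 0.00630. At least 1 TPM was reached by 13824 ± 358 and 12507 ± 46.1 genes.

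On the log2 scale with a pseudocount of 1, the largest rise was that of Ccr8, a chemokine receptor gene, which went from 9.51 ± 2.14 to 139 ± 2.34 TPM (log2 change 3.76, SE 0.17, limma adjusted p = 2.3e-05). Csf2, which encodes the cytokine GM-CSF, rose by 3.29 and Il12rb2, a subunit of the interleukin-12 receptor, by 3.25. Tnfrsf4 (3.18), the receptor-associated gene Ramp3 (3.15), the lactate exporter gene Slc16a3 (3.06) and the mitophagy gene Bnip3 (2.96) followed. Il17a, the gene of interleukin-17A, rose by 2.85 from 0.21 ± 0.105 to 7.76 ± 1.30 TPM, and the tubulin gene Tubb6 rose by 2.73. The order depends on the pseudocount: at 0.1, Il17a (4.71) and Csf2 (4.33) stood above Ccr8 (3.88), as they did by TPM ratio (37.0-fold, 16.2-fold and 14.6-fold higher). Tg, the thyroglobulin gene, rose by 3.18. Its span holds Sla, a lymphocyte adaptor gene on the opposite strand that rose by 1.31. In GENCODE M21, exons of Tg share 112 bases with Gm17140 on that strand and none with Sla. The annotation behind the deposited values is not given, so reads of Sla counted to Tg cannot be excluded. Exons of Il12rb2 overlap those of Serbp1 on the opposite strand over 40.0% of their length, and Serbp1 rose by 0.72.

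The largest falls included immunoglobulin, hemoglobin and sex-linked transcripts. Jchain, the joining chain of secreted antibodies, fell from 1123 ± 81.8 to 21.5 ± 3.45 TPM (log2 change -5.65, SE 0.15, limma adjusted p = 3.3e-06). The kappa constant region Igkc fell from 18539 ± 466 to 587 ± 63.8 TPM, Iglc2 changed by -4.94 and Igha by -4.56. Ahsp, which stabilizes alpha hemoglobin, changed by -5.06 and Hba-a1 by -4.64. S100a4, a calcium-binding protein gene, changed by -4.71, the Y-linked translation factor gene Eif2s3y by -4.70 and Ccl5 by -4.58. The small nucleolar RNA Snord3b3 stood at 1398, 2354 and 1630 TPM in the Mock sgRNA libraries and was listed at 0, 0 and 134 TPM in the SLC43A2 sgRNA libraries. Its call was lost with array weights (adjusted p = 0.0889; range over its alternatives 1.7e-05 to 0.0889). Iglc2, Hba-a1 and Snord3b3 have near-identical copies, so their levels are uncertain.

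**Figure D1:**
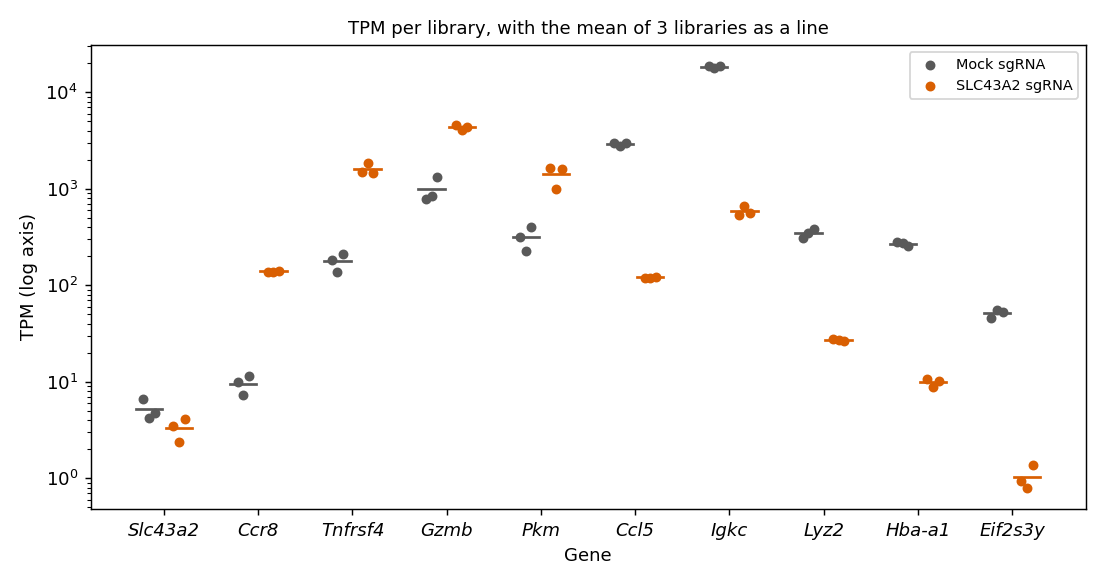
TPM of 10 genes in each of the 6 libraries on a log axis, with grey points for Mock sgRNA, orange points for SLC43A2 sgRNA and a line at each mean of 3 libraries. Ccr8, Tnfrsf4, Gzmb and Pkm were higher and Ccl5, Igkc, Lyz2, Hba-a1 and Eif2s3y lower in every SLC43A2 sgRNA library, while Slc43a2 did not pass the test.

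Of the 33 gene lists fixed before the data were examined, 29 had at least 5 measured members, and 18 passed an adjusted p of 0.05 with camera at its preset inter-gene correlation of 0.01 (9 higher, 9 lower). With a correlation estimated from the 6 libraries, 0 passed; the smallest adjusted p was 0.0570. By fry, which asks whether a list's genes move one way on balance, 21 passed. These were the same 18 and, each lower, the cytotoxic, type I interferon and Wnt target lists.

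Genes of methionine and one-carbon metabolism rose in libraries where the transcripts of B cells, myeloid cells and red blood cells, Y-linked transcripts, small nuclear and nucleolar RNAs and Malat1 were lower. In the methionine cycle and polyamine list, 9 of 16 measured members rose and 0 fell (median log2 change 0.71; camera adjusted p = 0.0052, and adjusted p = 0.498 with an estimated correlation). Cth, which makes cysteine from cystathionine, rose from 2.00 ± 0.0808 to 15.1 ± 1.72 TPM, and Odc1, which starts polyamine synthesis, from 165 ± 29.7 to 537 ± 126 TPM. Quantile normalization ended this list's call (adjusted p = 0.0501; range over its alternatives 0.00013 to 0.0501). In the serine and folate list, 9 of 12 rose, Psat1 (1.62) and Mthfd2 (1.48) the most, and 1, Mthfs, fell by 0.58 (median 1.24; adjusted p = 0.0020, and adjusted p = 0.368 with an estimated correlation). Among amino acid transporters 5 of 12 rose and 1, Slc38a9, fell by 0.58, and the list did not pass (median 0.40, adjusted p = 0.165). Slc7a5, which carries large neutral amino acids with Slc3a2, rose by 1.65, and Slc1a4 stood 6.29-fold higher in TPM and also passed. Across the 21 alternatives, Slc38a9 and Mthfs each lost their call in 6, with adjusted p up to 0.192 and 0.0758.

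The ATF4 list of the amino acid starvation response had 16 of 19 members up and 0 down (median 1.26; adjusted p = 1.8e-06, and adjusted p = 0.308 with an estimated correlation). Trib3 rose by 2.57 and Atf3 by 2.45. In glycolysis 16 of 17 members rose (median 1.62; adjusted p = 2.0e-07, and adjusted p = 0.368 with an estimated correlation), among them Slc16a3 and the pyruvate kinase gene Pkm, from 315 ± 86.3 to 1419 ± 356 TPM. In oxidative phosphorylation 18 of 27 nuclear-encoded members rose by smaller amounts (median 0.55; adjusted p = 5.4e-05, and adjusted p = 0.368 with an estimated correlation), with Uqcrc1 at 1.15 and Cycs at 1.06. The mitochondrially encoded mRNAs went the other way, with 7 of 13 down and 0 up (median -0.80; adjusted p = 0.0075, and adjusted p = 0.479 with an estimated correlation). Of these, mt-Nd6 changed by -1.47 and mt-Nd4 by -1.38. Removing trends with transcript length and GC ended the mitochondrial call (median -0.21, adjusted p = 0.297; range over its alternatives 0.0017 to 0.297), and without SLC43A2 sgRNA replicate 2 the median was -0.45. In the same libraries that held these rises, the B cell, plasma cell, myeloid, erythroid, Y-linked, small nuclear and nucleolar and Malat1 transcripts were lower and the protein-coding share higher.

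T cell activation genes rose, with 12 of 16 members up and 3 down (median 1.36; adjusted p = 0.00054, and adjusted p = 0.368 with an estimated correlation). Tnfrsf9, the costimulatory receptor 4-1BB, rose from 184 ± 50.7 to 1106 ± 194 TPM, while Cd40lg changed by -1.30. B cell, myeloid, erythroid, Y-linked and small nuclear and nucleolar transcripts were lower in the same libraries. Among STAT5 targets 11 of 15 rose and 0 fell (median 1.13; adjusted p = 4.2e-05, and adjusted p = 0.368 with an estimated correlation), led by Cish (2.54), a feedback inhibitor of cytokine signaling, and Il2ra (2.21), the interleukin-2 receptor alpha chain. In the regulatory T cell list 5 of 12 rose and 1 fell (median 0.53; adjusted p = 0.0116, and adjusted p = 0.379 with an estimated correlation). Its median moved to 2.16 among genes of at least 5 TPM and to 0.88 with quantile normalization. The members that rose were Ccr8, Tnfrsf4, Ctla4, Il2ra and Tnfrsf18, which activated T cells also express, and Tnfrsf4 and Il2ra are also in the T cell activation list. Ikzf2 changed by -1.15, and Foxp3, the lineage factor, stood at 14.6 and 10.4 TPM in the Mock and SLC43A2 sgRNA groups (adjusted p = 0.0799). Foxp3 and Tnfrsf18 were named after their values were seen.

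Naive and memory genes fell in 10 of 14 cases and rose in 3 (median -0.97; adjusted p = 0.0092, and adjusted p = 0.504 with an estimated correlation). S1pr1, which lets T cells leave lymphoid tissue, changed by -3.07 and the quiescence factor Klf2 by -2.59, while the homing receptor gene Ccr7 rose by 2.44 and Satb1 by 1.48. The B cell list (median -3.12), myeloid genes and Y-linked genes fell in the same libraries, and B cells also express some naive and memory genes, such as Klf2 and S1pr1. Cytotoxic effector genes went both ways, with 10 of 22 up and 8 down, and the list did not pass (median 0.22, mean -0.15, adjusted p = 0.699). Its camera direction was up and its fry direction down (fry adjusted p = 0.0123). Granzyme B, Gzmb, rose from 990 ± 299 to 4328 ± 277 TPM and Tbx21, the T-bet gene, by 2.19, while Gzmk changed by -3.66 alongside Ccl5. Exhaustion genes were split 4 up and 4 down of 15 (median 0.31, adjusted p = 0.577), with Ctla4 (2.34) and Cd200 (1.43) up and Tox (-1.95) and Tox2 (-1.57) down.

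T cell identity genes changed little as a list, with 3 of 20 up and 5 down (median -0.23, adjusted p = 0.504; median -0.38 and adjusted p = 0.0287 under quantile normalization, range over its alternatives 0.0287 to 0.70). Bcl11b changed by -1.65 and Skap1 by -1.23. The receptor constant region Trbc2, which has a near-identical copy, stood at 3098 ± 103 and 2454 ± 142 TPM; its log2 change of -0.34 turned to 0.12 once length and GC trends were removed.

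The interferon gamma list had 16 of 23 members up and 2 down (median 1.09; adjusted p = 2.4e-05, and adjusted p = 0.368 with an estimated correlation). The GTPase genes Igtp (2.31) and Gbp5 (2.26) rose the most, and Ciita, the class II transactivator, changed by -2.19 and the immunoproteasome gene Psmb10 by -0.61, a call lost without SLC43A2 sgRNA replicate 1 (adjusted p = 0.0642) or 3 (adjusted p = 0.0679; lowest over its alternatives 0.0022). The type I interferon list had 2 of 22 up and 9 down and did not pass camera (median -0.38, adjusted p = 0.0880). It passed fry (down, adjusted p = 0.0304). The camera adjusted p was 0.0150 with length and GC trends removed, with a range over its alternatives of 0.0150 to 0.437. The list's median turned to 0.07 among genes of at least 5 TPM. Usp18 rose by 1.66, while Ifit3 changed by -1.91 and Rigi by -1.62. Lower B cell, myeloid, erythroid and Y-linked transcripts went with these changes.

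Markers of B cells, plasma cells, macrophages, neutrophils and NK cells fell, while the 6 measured of 15 listed dendritic cell genes were split. All 15 measured B cell genes fell (median -3.12; adjusted p = 7.3e-12, and adjusted p = 0.0906 with an estimated correlation), among them Cd79a, from 151 ± 22.8 to 6.74 ± 0.226 TPM. In the plasma cell list 11 of 14 fell and 1, Xbp1, rose by 1.14 (median -3.19; adjusted p = 1.8e-07, and adjusted p = 0.0570 with an estimated correlation). Immunoglobulin transcripts made up 4.54% ± 0.298 of the Mock sgRNA libraries and 0.212% ± 0.0117 of the SLC43A2 sgRNA libraries (SD, n = 3 each; exact permutation p = 0.1). Macrophage and monocyte genes fell in 15 of 17 cases and rose in 1, Arg1 (median -2.44; adjusted p = 1.8e-07, and adjusted p = 0.137 with an estimated correlation). The lysozyme gene Lyz2 went from 347 ± 38.2 to 26.9 ± 0.575 TPM. Neutrophil genes fell in 11 of 13 cases (median -2.04; adjusted p = 9.4e-07, and adjusted p = 0.0570 with an estimated correlation), with Elane at -3.15 and S100a8 at -2.24.

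NK cell genes fell in 8 of 10 cases (median -1.15; adjusted p = 0.00066, and adjusted p = 0.200 with an estimated correlation), with Klrc2 at -2.07 and Klrd1 at -1.42. The NK cell median was -0.73 among genes of at least 5 TPM. Erythroid genes fell in 9 of 11 cases (median -3.47; adjusted p = 9.4e-07, and adjusted p = 0.0570 with an estimated correlation). Their median was -1.63 with no filter and -1.43 without antigen receptor, mitochondrial and hemoglobin genes, where the plasma cell median was -2.07. MHC class II genes, which B cells and myeloid cells express, fell in 10 of 11 cases (median -2.69; adjusted p = 2.1e-07, and adjusted p = 0.299 with an estimated correlation), with Cd74 going from 1076 ± 172 to 125 ± 11.3 TPM. Dendritic cell genes were split 2 up and 2 down of 6 (median 0.34, camera adjusted p = 0.690). From Mock sgRNA to SLC43A2 sgRNA, Irf8 (73.9 to 288 TPM) and Bst2 (280 to 575 TPM) rose. The low genes Cd209a (2.62 to 0.017 TPM) and Siglech (1.78 to 0.33 TPM) fell. The list's median turned to -0.10 without the filter on low values. Quantile normalization ended the Siglech call (limma adjusted p = 0.108, lowest over its alternatives 0.0027).

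Few transcripts of tumor cells or stroma were measured. Of the hepatocyte and hepatoma list 3 genes reached 1 TPM; Afp, the alpha-fetoprotein gene, stood at 5.50 and 3.69 TPM in the Mock and SLC43A2 sgRNA groups (adjusted p = 0.161), Trf changed by -2.93, and Alb was listed at 0 in all 6 libraries. Of the endothelial list 3 genes were measured, with Eng (1.46) and Egfl7 (1.15) up and Pecam1 (-1.37) down. In the fibroblast list 0 genes were measured. The photoreceptor and retina list was included because the extraction text of the labels speaks of retinas; 3 of its genes were measured and 0 passed. Afp was named after its values were seen.

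The other lists did not pass camera, and of these only Wnt targets passed fry (down, adjusted p = 0.0471). Among histone and DNA methyltransferases, which use the methionine product S-adenosylmethionine, 5 of 27 rose and 10 fell (median -0.21, adjusted p = 0.395). The arginine methyltransferase genes Prmt1 (1.79) and Prmt5 (1.31) rose, while the H3K4 methyltransferase genes Setd1b (-1.67) and Kmt2c (-1.61) fell. Cell cycle genes were split 7 up and 6 down of 24 (median 0.27, adjusted p = 0.579), with Mcm6 (1.40) and Rrm2 (1.25) of DNA replication up and the mitotic genes Ccnb2 (-1.23) and Mki67 (-1.11) down. Of 7 Wnt targets 5 fell, Axin2 (-1.74) and Rnf43 (-1.33) the most, and 1, Myc, rose by 1.41 (median -0.72, adjusted p = 0.165). Immediate early and stress genes had 3 of 18 up and 3 down (median -0.03, mean 0.02, adjusted p = 0.920), with Ier3 (1.41) and Hspa8 (0.72) up and Hspa1b (-0.83) and Btg2 (-0.70) down. Quantile normalization ended the Hspa1b call (adjusted p = 0.0779; lowest over its alternatives 0.0018). T cell receptor scaling (adjusted p = 0.0596) and leaving out Mock sgRNA replicate 1 (adjusted p = 0.0573) ended that of Btg2 (lowest 0.00047). Cytosolic ribosomal protein genes had 2 of 32 up and 5 down (median -0.07, adjusted p = 0.690), with Rpl4 at 0.57 and Rpl10a at -0.63. The medians of these last lists turned to 0.14 and 0.11 with libraries scaled to their T cell receptor transcripts.

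**Figure D2:**
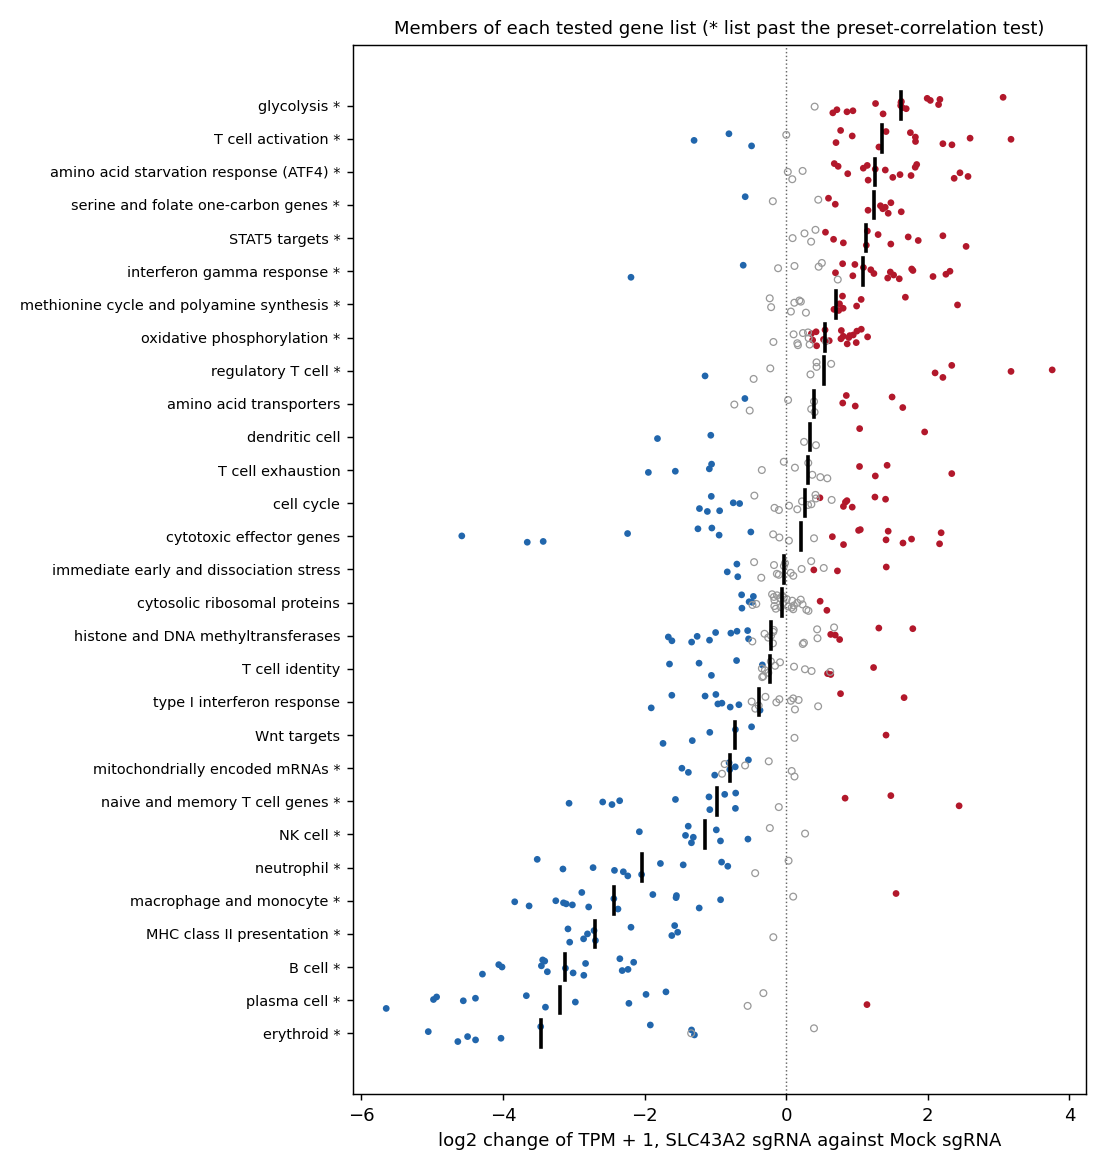
Log2 change of TPM + 1 between SLC43A2 sgRNA and Mock sgRNA for each measured member of the 29 tested lists, ordered by median. Filled points passed the test for the single gene (red higher, blue lower), open points did not, black bars are list medians and asterisks mark the 18 lists past the preset-correlation test. Medians ran from -3.47 for erythroid genes to 1.62 for glycolysis, and the small medians of the immediate early and ribosomal lists changed sign under other scalings.

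Adjusted over the list alone, the counts of genes that rose and fell were the same as over all genes for 19 of the 29 tested lists and differed by at most 2 genes in the other 10. Adjusted over the list alone, 10 serine and folate genes, 18 interferon gamma genes and 20 oxidative phosphorylation genes rose, and 12 plasma cell genes and 8 mitochondrial mRNAs fell. In the same terms, 4 T cell identity genes rose and 6 fell, 11 cytotoxic and 8 cell cycle genes rose, 2 immediate early genes rose, and 3 ribosomal protein genes fell. Some values given above moved by more than 1.5 times under an alternative. Removing length and GC trends moved Ikzf2 to -0.71, Klrd1 to -0.84, Mki67 to -0.71 and mt-Nd6 to -0.59, and Slc38a9 to -0.23, which ended its call. A pseudocount of 0.1 moved, among others, Il17a to 4.71, Slc1a4 to 2.44, Tox2 to -2.53, Ciita to -3.33 and Axin2 to -2.77. The samples carry replicate numbers but nothing in the labels says whether they came from separate mice, so the p-values measure only the spread between these 6 samples, which may be technical.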

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

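Scaling to T cell receptor transcripts, removal of genes of other cell types and removal of length and GC trends were chosen only after the results were seen. The number of genes changed stayed within 1.5 times 6199 in all 21 alternatives, from 4262 without SLC43A2 sgRNA replicate 3 to 7477 with array weights. Slc43a2 stayed below Mock sgRNA and short of the threshold in the 20 alternatives that could give it, from -0.65 to -0.20 (adjusted p 0.0757 to 0.405); at a mean of at least 5 TPM it is not tested. The list count was 18 in most alternatives and fell to 0 with an estimated correlation. It was 12 of 23 without genes of other cell types, which leaves fewer lists to test, and 21 by fry. Deviations of same-numbered libraries from their group means correlated at 0.001, 0.061 and -0.031, so no shared shift was seen. This cannot show whether the numbers pair samples, which the labels do not say. With the replicate block 6357 genes and 18 lists passed and Slc43a2 differed by -0.52 (limma adjusted p = 0.0757).

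Of 2259 values of 110 named genes under the alternatives, 2208 kept direction and side of the threshold, 49 lost their call and 2 turned sign: Sag (0.033, quantile normalization) and Trbc2 (0.12, length and GC trends removed). Of 599 list medians, 584 kept both, 2 lost their call, 2 gained one and 11 turned sign, all 11 in lists that did not pass camera. These were dendritic cell (-0.10, no filter), type I interferon (0.066, mean of at least 5 TPM), ribosomal proteins (0.11 with T cell receptor scaling, 0.14 with length and GC trends removed) and immediate early genes (0.063 at a mean of at least 5 TPM, 0.032 with median-of-ratios scaling, 0.0034 with array weights, 0.14 with T cell receptor scaling). With single libraries left out, immediate early genes ranged from -0.16 to 0.13 and ribosomal proteins from -0.13 to 0.040. The cause was not tested. T cell receptor scaling moved the median of all genes by 0.15 and quantile normalization by 0.11. The unknown depth limits what can be said of low genes.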

Other observations

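The tests in this part were chosen only after the data were seen, apart from the count over other splits of the samples.

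Genes of T helper cytokines, a group looked at after the values were seen, were in part higher in SLC43A2 sgRNA. Of 22 such genes 17 were measured, 12 rose and 2 fell with limma. Interleukin-2 (Il2) rose from 3.34 ± 1.36 to 20.4 ± 1.12 TPM, Il4 from 7.21 ± 1.44 to 23.3 ± 2.76, Il21 from 3.87 ± 0.326 to 15.8 ± 1.13 and Lif from 6.58 ± 1.76 to 32.0 ± 2.80 (SD, n = 3 each). Il22 was listed at 0 in all 3 Mock sgRNA libraries and had a mean of 5.46 ± 0.585 TPM in SLC43A2 sgRNA. Ifng rose by 1.41, Il5 by 2.15 and Il17f by 2.19, while Ltb, which B cells also express, changed by -1.81 and Csf1 by -0.86. Il10, Tgfb1 and Tnfsf11 did not pass, and the group was not tested as a set. In the same libraries the B cell list (median -3.12) and the Y-linked Eif2s3y (51.4 to 1.03 TPM) fell.

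Among 122 families of at least 10 genes sharing a symbol stem, 15 passed camera with its preset correlation (10 higher, 5 lower) and 0 passed with an estimated one. Mitochondrial ribosomal proteins rose, 36 of 50 with the stem Mrpl and 19 of 29 with Mrps, as did 11 of 14 proteasome subunits with the stem Psmd and 34 of 54 translation factor genes with the stem Eif, of which 3 fell (Eif2s3y, Eif4ebp2 and Eif4ebp3, named after their values were seen). The lower families included Clec, with 9 of 13 genes down and 2 up (Clec4e and Clec7a), and Trim, with 15 of 33 down and 2 up (Trim13 and Trim23), all 4 named likewise. Immunoglobulin V genes fell in 163 of 178 cases and rose in 0, while of 133 T cell receptor V genes 12 rose and 10 fell.

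The glycolysis, ATF4 and T cell activation lists rose together with a loss of B cell, myeloid and erythroid transcripts. If fewer other cells had raised every T cell gene alike, T cell identity genes would rise as much. Their median log2 change was -0.23. In every SLC43A2 sgRNA library each list's score exceeded the T cell identity score by at least 1.26. In the Mock sgRNA libraries it did so by at most 0.11. Scores were medians of log2 values centred on each gene's Mock sgRNA mean, so Mock sgRNA scores are small by construction. The 3 lists were picked because they had risen, so this gap was set in advance and adds no support. After removal of length and GC trends all 3 lists stayed past the threshold, with a smallest median of 1.16. The T cell identity median argues against fewer other cells as the whole cause of the 3 rises. The medians after trend removal argue against length and GC trends as the whole cause. A changed state or mix of the T cells may remain, as may a difference between the mice that the sex-linked transcripts point to. The guide itself is 1 of the open explanations and cannot be separated from such a difference in this design. The makeup of the libraries differed too, and neither check addresses it. Protein-coding transcripts made up 77.9% of the Mock sgRNA and 86.6% of the SLC43A2 sgRNA libraries, and small nuclear and nucleolar RNAs 3.15% and 1.04%.

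In SLC43A2 sgRNA, sex-linked transcripts stood out once the data were seen: the Y-linked Eif2s3y fell from 51.4 ± 5.39 to 1.03 ± 0.297 TPM, Ddx3y stood 38.6-fold lower, Uty 52.1-fold and Kdm5d 12.3-fold, and Xist rose by 1.19, from 4.31 ± 1.11 to 11.01 ± 1.20 TPM; Xist shares exon bases with Tsix on the opposite strand, which rose too. Suppose that all cells came from animals of 1 sex and only the share of T cells differed. Y-linked genes would follow T cell identity genes if only T cells expressed them, and stay about level if all cells did so alike. Their score minus the T cell identity score was at most -2.98 in every SLC43A2 sgRNA library and at least -0.42 in every Mock sgRNA library. Scores were centred on each gene's Mock sgRNA mean, so the Mock sgRNA values are small by construction. T cell identity genes changed little (median -0.23), so the Y-linked genes did neither. In a further case, Y-linked RNA came mainly from the cells that were lost and would fall as their markers did. Medians of the lower non-T cell lists ran from -1.15 (NK cell) to -3.47 (erythroid). The comparison with T cell identity genes cannot exclude that case. A different share of male and female cells in the groups is a candidate explanation that the rise of Xist is consistent with. Tumor cells as the source of the Y-linked RNA would bring hepatoma transcripts, but 17 of the 22 hepatocyte and hepatoma genes, Alb, Ttr, H19 and Krt8 among them, were listed at 0 in all 3 Mock sgRNA libraries, which argues against it, although Trf of the same list fell from 21.8 to 1.86 TPM and Afp stood at 5.50 and 3.69 TPM without passing. Whether male cells came from host mice or were transferred was not tested, and the labels used here give no sex.

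Of the 27 histone and DNA methyltransferases, 10 fell, among them Setd1b and Kmt2c, and 5 rose, and the list did not pass (median -0.21). Those that fell have long transcripts (median 9481 bases, against 3236 bases for tested protein-coding genes). Across 10442 protein-coding genes, which are not independent replicates, the log2 change correlated with transcript length at -0.19 (Spearman). After removal of length and GC trends 8 of the 10 stayed past the threshold and their median went from -1.04 to -0.74, while that of all 27 went from -0.21 to -0.07. The 10 were picked because they had fallen, so their values cannot decide, and length and GC trends stay open as a cause, as does a change in cell makeup, which was not tested.

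The 6 samples can be split 3 against 3 in 10 ways, too few for a share under 0.05. The real split gave 6199 genes and 18 lists, and the other splits 1 to 6 genes and 6 to 14 lists. Each other split mixes libraries of both groups, so the group difference adds to the spread within its groups. A low gene count was therefore set in advance, and the gene counts cannot gauge chance. Lists passed at the preset correlation even in splits where at most 6 genes did. In both cases 1 of the 10 splits, the real one, gave as many.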
